A study of Mus musculus with 13 samples.

How the data were processed

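Messenger RNA of NK cells was measured by RNA sequencing in 13 samples, and the deposited table held 11989 genes. Per the labels' protocols, strand-specific libraries were made from poly(A) RNA and pooled after first-strand synthesis. The genome build was mm10 per the submitters' notes, and no source used here gives the aligner, counting tool or gene annotation. The table is named as counts, but the deposited values are log2 values of quantile-normalized counts with 1 added, a unit read from the values themselves. They ran from 0 to 17.92, and the sorted values of the libraries nearly coincided (median spread 0.009). Of the values under 6, back-transformed and multiplied by 13, 91.6% lay within 0.05 of a whole number, as means over 13 whole counts do.

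The comparisons had been planned with a count model. Because the deposited unit was log2, the alternative written down for that case was used, which is limma on the values as deposited, with the same samples and contrasts. Samples, groups, comparisons, gene lists and the rule for named genes were fixed before the data were examined. The filter and the variance trend were chosen after the distribution of the values had been seen and before any test result. For 2 naive anti-NK1.1 samples (replicates 1 and 4) the stimulation label gave only the 6 hours, and their titles gave the group.

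One model with 5 groups was fitted to all 13 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend (8 residual and 6.3 prior degrees of freedom). Genes needed a back-transformed value of at least 10 in at least 2 libraries, which removed 446 and left 11543. The 7 contrasts were each tested two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Of the gene lists, 25 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Adjustment over the list alone used the members' p-values only. Named genes were the 8 largest increases and 8 largest decreases per contrast among called genes with a mean of at least 20 CPM and no overlap between the groups, the 4 members of each list with the smallest p, and a panel of 20 genes. Unnamed gene models were left out, and some genes that the rule allows are not printed. Coordinates come from the GENCODE annotation of mm10, which held 11983 of the 11989 identifiers, 11940 of them protein coding.

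Quantile normalization gives every library the same sum, so depth was recovered from the order of values: successive distinct values of a library stand for 0, 1, 2 and more reads. This holds up to rank 7000 by level. At the median gene the mean of the recovered reads was 193.69 and the back-transformed value 193.68, and at the upper quartile 648.92 and 660.98. In simulated data at least 82.1% of 7000 genes were recovered exactly, with a largest error of 4 reads. For a gene without a read in a group, the fold was computed against a floor of 3 reads per library, and floors cover counting error only.

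The test was checked on simulated data with 200 of 11543 genes changed, in 5 simulations per contrast. For the naive response it recovered 33.4% of genes changed by 1 on the log2 scale and 87.6% of those changed by 2, and for the difference between responses 5.8% and 57.6%. False calls were 3.1% to 6.2% of calls, over 5% for the naive response (6.2%) and HD against naive unstimulated (5.5%). Camera called 0 of 125 unchanged lists in each contrast. Simulated genes were independent, so this cannot check lists with correlated members. Alternatives were a stricter and no filter, limma's treat against a fold change of 1.5, robust moderation, the compared groups alone, replicate number as a block and each library left out. Added after the data had been seen were no variance trend, an offset of 8, library pool as a factor, median-ratio scaling, and recovered reads tested with limma or limma-voom. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.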

Results

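To describe how culture in interleukin-15 (IL-15), a cytokine that sustains survival and growth of natural killer (NK) cells, changes their response to an activating receptor, RNA was sequenced from 13 samples of NK cells. The cells came from the spleen of wild-type C57BL/6 mice, and each sample gave 1 library. The labels place the samples in 5 groups. Naive cells, for which the labels give no culture time, were left unstimulated (n = 3) or stimulated with anti-NK1.1 for 6 hours (n = 3). Cells cultured for 72 hours in IL-15 were labelled LD or HD, abbreviations that the labels do not spell out. LD cells were sequenced only after anti-NK1.1 (n = 2), and HD cells without stimulation (n = 2) and after anti-NK1.1 (n = 3). Anti-NK1.1 binds the activating receptor encoded by *Klrb1c* (chromosome 6, 128778485 to 128789215, minus strand, mm10). The labels do not say whether the replicates came from separate animals or cultures, so the p-values below measure the spread between these samples, which may be technical.

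The table held 11989 genes, of which 11543 passed the filter on low values. Its values were log2 of normalized counts brought to 1 common distribution, so depth could not be read from a library's sum. Reads recovered from the order of the values gave 112 to 463 reads for the median gene of a library. The deepest library, LD replicate 1, lay at 2.39 times the mean of the libraries, and the shallowest, naive unstimulated replicate 4, at 0.578 times. Between 155 and 809 genes per library had no read. Libraries of 1 group correlated with r between 0.956 and 0.974 across genes, and libraries of different groups with r between 0.808 and 0.943; genes are not independent replicates. In a principal component analysis of the tested genes, components 1 and 2 held 43.3% and 21.5% of the variance, and libraries lay by group. The file header gave 2 library pools. All 6 naive libraries and LD replicate 3 were in pool 2, and LD replicate 1 and all 5 HD libraries were in pool 1.

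**Figure D1:**
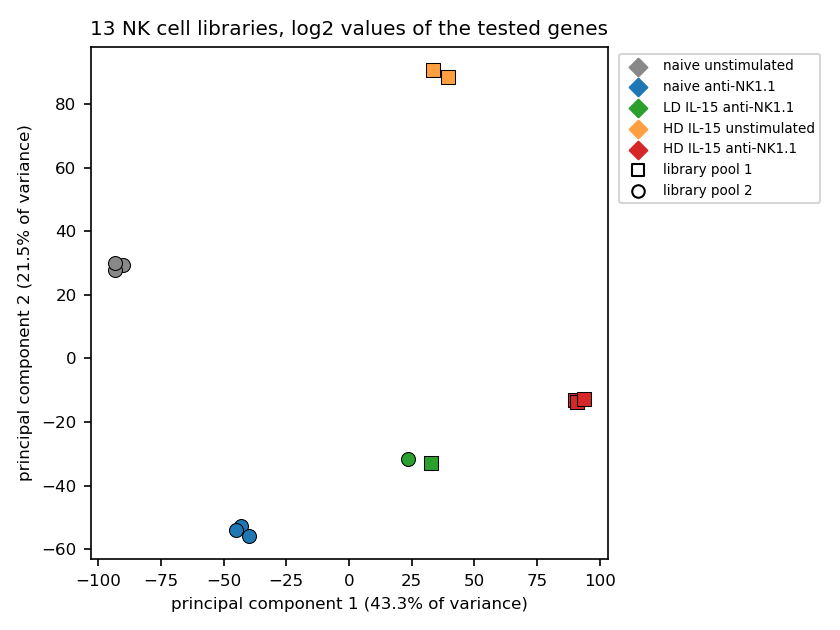
Principal component analysis of the log2 values of 11543 genes in 13 libraries, with component 1 (43.3% of the variance) on the x axis and component 2 (21.5%) on the y axis, both in log2 units. Each point is 1 library, coloured by group, with squares for pool 1 and circles for pool 2; the libraries of each group lie closer to each other than to those of the other groups.

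Changes below are log2 fold changes ± standard error from 1 limma model of all 13 libraries, with Benjamini-Hochberg adjusted p-values. Levels are counts-per-million (CPM) of the back-transformed values (mean ± SD). For each gene called higher or lower below, the libraries of both groups did not overlap, except *Csf2* in naive cells. Gene lists were fixed before the data were examined. A list's camera test compares its members with all other tested genes, first with a preset correlation of 0.01 between members.

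For the naive response, naive anti-NK1.1 libraries (n = 3) were compared with naive unstimulated libraries (n = 3). With anti-NK1.1, *Ifng*, which encodes the cytokine interferon-γ (chromosome 10, 118441046 to 118445892, plus strand), rose from 82.6 ± 15 to 201 ± 26.1 CPM (1.29 ± 0.23, adjusted p = 8.53e-04). Chemokine genes rose as well, with *Ccl3* at 1.95 ± 0.26, *Ccl4* at 2.15 ± 0.25 and *Xcl1* at 1.81 ± 0.31. *Klrb1c*, the gene of the ligated receptor, fell by 3.43 ± 0.18 (adjusted p = 2.19e-08), from 715 ± 88.1 to 65.9 ± 3.31 CPM. In all, 1678 genes were higher and 1698 lower after stimulation, out of 11543 tested.

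The sharpest increases were those of *Ppp2r2c*, a regulatory subunit of protein phosphatase 2A (7.4 ± 0.57), and *Fam83g* (6.84 ± 0.76), both with few reads in unstimulated cells. They were followed by *Pmepa1* (6.33 ± 0.30), *Trib3*, a pseudokinase induced in amino acid and endoplasmic reticulum stress (5.85 ± 0.42), the interferon-γ-induced chemokine *Cxcl9* (5.57 ± 0.54), the protease inhibitor *Serpine2* (5.08 ± 0.42), *AA467197* (4.75 ± 0.36) and the zinc finger transcription factor *Egr2* (4.69 ± 0.28, adjusted p = 6.64e-08). The sharpest decreases included 2 genes linked to Notch signalling, *Dtx1* (-5.81 ± 0.63) and the repressor *Hes1* (-3.59 ± 0.28). The others among the 8 were the AP-1 subunit *Fosb* (-4.79 ± 0.39), the phosphatase *Acp5* (-4.38 ± 0.31), *Aoah*, which degrades lipopolysaccharide (-4.14 ± 0.27), *Pglyrp2* (-4.05 ± 0.33), the atypical inhibitor of NF-κB *Nfkbiz* (-3.76 ± 0.27) and *Klrb1c*. *Il2ra*, the high-affinity interleukin-2 receptor chain, rose by 3.89 ± 0.43, and *Cish*, a feedback inhibitor of cytokine signalling, by 2.42 ± 0.24. *Eomes*, a transcription factor of mature NK cells, rose by 0.92 ± 0.22, whereas *Tbx21*, which encodes T-bet, changed by -1.30 ± 0.21. The natural cytotoxicity receptor gene *Ncr1* changed by -2.81 ± 0.23, the granzyme gene *Gzma* by -1.52 ± 0.23 and the proliferation marker *Mki67* by -1.20 ± 0.29. *Csf2*, which encodes the growth factor GM-CSF, had 39 reads over the stimulated and 1 over the unstimulated libraries (adjusted p = 0.0141). *Tnf* (-0.12 ± 0.28, adjusted p = 0.782), *Gzmb* (-0.16 ± 0.24, adjusted p = 0.648), perforin gene *Prf1* (-1.10 ± 0.41, adjusted p = 0.0549), the orphan nuclear receptor *Nr4a1* (-0.27 ± 0.21, adjusted p = 0.364), *Myc* (-0.49 ± 0.22, adjusted p = 0.112) and the survival gene *Bcl2* (0.55 ± 0.24, adjusted p = 0.0986) did not pass the threshold.

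Genes of amino acid transport, serine synthesis and the ATF4 response rose together: 17 of 19 tested members were higher and 0 lower (18 and 0 adjusted over the list alone) (camera, adjusted p = 4.32e-17, and 0.0115 with estimated correlation). Among them were *Mthfd2*, a mitochondrial folate enzyme (4.53 ± 0.22), the asparagine synthetase *Asns* (3.52 ± 0.24) and the amino acid transporter *Slc7a5* (4.05 ± 0.28). Of the ribosome biogenesis list, which holds nucleolar factors such as *Rrp12* (1.73 ± 0.27), 12 of 24 tested members were higher and 0 lower (16 and 0 adjusted over the list alone) (camera, adjusted p = 3.44e-06, and 0.0236 with estimated correlation). Cell cycle genes moved the other way. For the S phase list 16 of 26 tested members were lower and 1 higher (19 and 2 adjusted over the list alone) (camera, adjusted p = 3.44e-06, and 0.00668 with estimated correlation). For the G2/M list 15 of 26 tested members were lower and 0 higher (19 and 0 adjusted over the list alone) (camera, adjusted p = 5.30e-07, and 0.00668 with estimated correlation). Examples were the cyclins *Ccna2* (-2.16 ± 0.24) and *Ccnb2* (-2.09 ± 0.24).

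Of the NK cell receptors and adaptors, 19 of 29 tested members were lower and 1 higher (20 and 1 adjusted over the list alone) (camera, adjusted p = 5.34e-09), a call lost at adjusted p = 0.0701 with an estimated correlation. Besides *Klrb1c* they included its neighbour *Klrb1a* (-3.20 ± 0.22) and the inhibitory receptor *Klrg1* (-3.35 ± 0.23). Members of the Klrb1 and Klra families have similar sequences and can share reads. The cytotoxic granule list had 8 of 23 lower and 3 higher, 9 and 3 adjusted over the list alone (camera, adjusted p = 0.0125, and 0.209 with estimated correlation), led by *Nkg7* (-2.76 ± 0.20), a granule membrane protein, and *Fasl* (-1.63 ± 0.17). In the effector cytokine list the members stood at 7 of 16 higher and 1 lower, 7 and 2 adjusted over the list alone (camera, adjusted p = 0.0125, and 0.320 with estimated correlation), and *Ccl1* rose by 2.97 ± 0.22 while *Osm*, which encodes oncostatin M, changed by -3.08 ± 0.29. Cytokine receptors and STATs other than those of IL-15 had 7 of 21 higher and 1 lower, 7 and 1 adjusted over the list alone (camera, adjusted p = 0.0112, and 0.0640 with estimated correlation). These included *Il10ra* (1.82 ± 0.23) and *Il21r* (2.35 ± 0.30). Quiescence-associated genes, such as *Klf2* (-3.08 ± 0.18) and *Foxo3* (-1.75 ± 0.23), had 7 of 16 lower and 0 higher, 7 and 0 adjusted over the list alone (camera, adjusted p = 0.00110, and 0.179 with estimated correlation). Oxidative phosphorylation genes had 6 of 44 lower and 1 higher, 4 and 1 adjusted over the list alone (camera, adjusted p = 0.0107, and 0.581 with estimated correlation). B cell markers had 2 of 8 lower and 0 higher, 2 and 0 adjusted over the list alone (camera, adjusted p = 0.0282, and 0.179 with estimated correlation), with *Cd22* at least 40.0-fold lower, and summed to 16.9 ± 2.71 CPM without and 4.26 ± 1.76 with stimulation. T cell markers summed to 83.1 ± 5.6 without and 43.2 ± 5.34 CPM with stimulation; their list had 2 of 5 lower and 0 higher, 2 and 0 adjusted over the list alone, without a call (camera, adjusted p = 0.205). Erythroid and platelet markers summed to 556 ± 194 and 1347 ± 725 CPM (replicate 4, 2181), most of it *Car2*, singled out after its values were seen (1.67 ± 0.34, 366 ± 149 and 1222 ± 718); their list had 1 of 9 higher and 1 lower, 1 and 1 adjusted over the list alone, without a call (adjusted p = 0.542).

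The remaining lists gave no camera call. The immediate early and NFAT/NF-κB list held genes that moved both ways, with 14 of 30 lower and 9 higher, 14 and 9 adjusted over the list alone (camera, adjusted p = 0.205), and so did the activation and checkpoint receptors, with 8 of 19 higher and 5 lower, 9 and 5 adjusted over the list alone (adjusted p = 0.109). In the latter, *Crtam*, an adhesion receptor of activated lymphocytes (4.17 ± 0.16), and *Tnfrsf9*, which encodes the costimulator 4-1BB (2.97 ± 0.19), were higher, and *Cd7* (-2.60 ± 0.23) and the early activation marker *Cd69* (-1.86 ± 0.20) lower. The IL-15 receptor and STAT5 list had 6 of 21 higher and 5 lower, 7 and 6 adjusted over the list alone (adjusted p = 0.534), including the proapoptotic gene *Bcl2l11* (4.04 ± 0.25) and *Stat5a* (2.68 ± 0.21). Without naive anti-NK1.1 replicate 1 the calls of *Csf2* (adjusted p = 0.0598) and of the B cell markers (0.0711) were lost, and without replicate 4 those of *Csf2* (0.0645) and of the oxidative phosphorylation list (0.0837).

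The same stimulus was then examined in cells cultured in HD IL-15, with 3 anti-NK1.1 and 2 unstimulated libraries, all in pool 1. *Ifng* rose from 60.3 ± 7.92 to 3349 ± 315 CPM (5.80 ± 0.26, adjusted p = 3.08e-09). *Tnf*, the gene of tumor necrosis factor, rose by 4.41 ± 0.31, *Ccl3* by 5.01 ± 0.29, *Ccl4* by 4.71 ± 0.28 and *Xcl1* by 5.31 ± 0.35 (adjusted p = 1.55e-07). *Csf2* rose by 4.14 ± 0.79 from 23 reads in the unstimulated libraries. *Klrb1c* fell by 3.92 ± 0.20 (adjusted p = 1.20e-08). In all, 1834 genes were higher and 1989 lower.

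**Figure D2:**
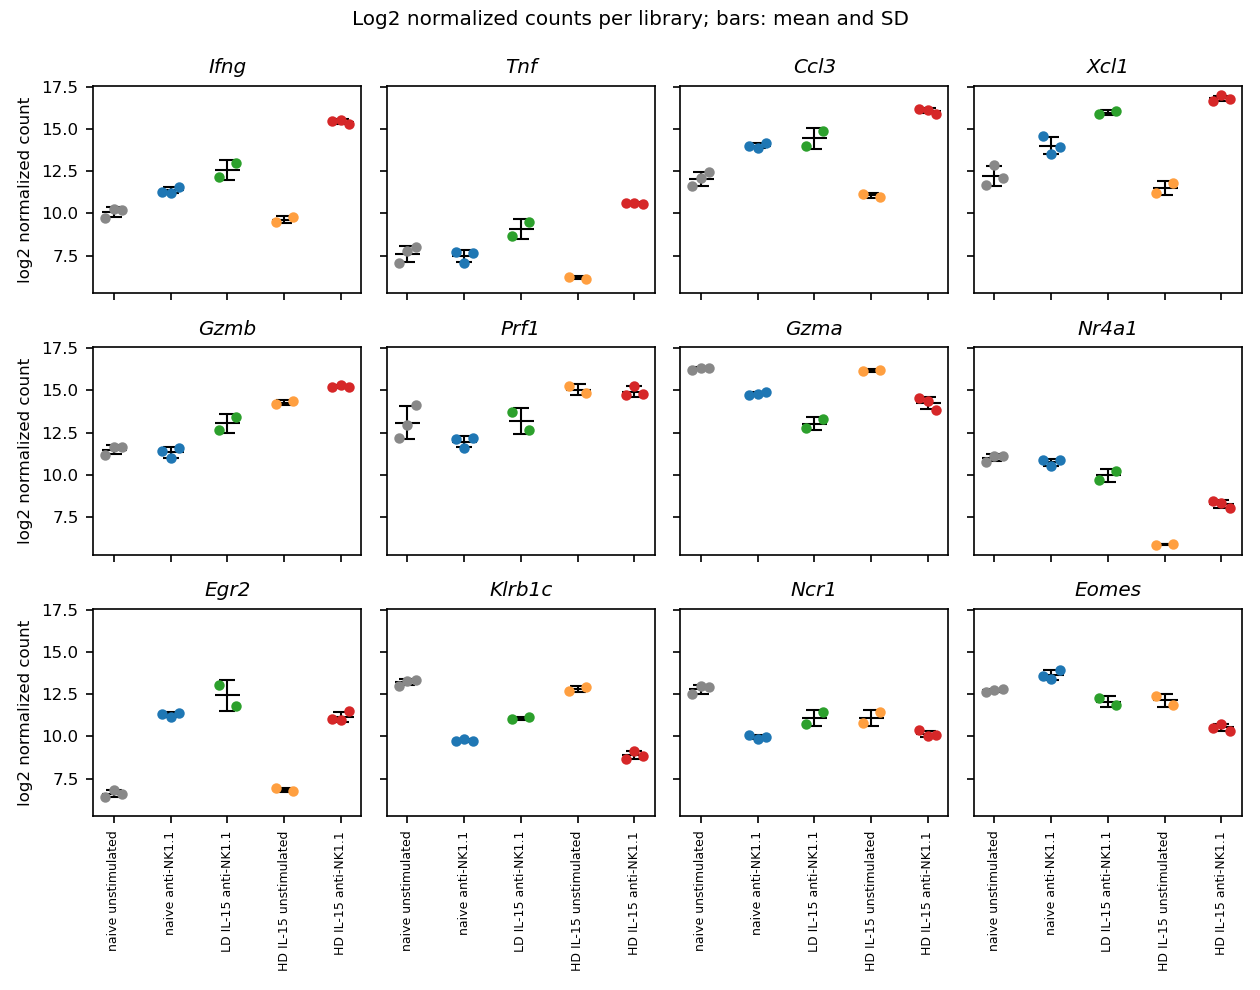
Levels of 12 genes in each of the 13 libraries, as log2 normalized counts on the y axis, with 1 panel per gene and the 5 groups on the x axis. Points are libraries, bars the mean and SD of a group; *Ifng* lies above 15 in the HD anti-NK1.1 libraries and below 13 in all other libraries.

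The transcriptional repressor *Bcl11a* had no read in either unstimulated library and was at least 79.5-fold higher after stimulation. The further leading increases were *Ccl1*, a chemokine that signals through CCR8 (7.38 ± 0.25), *Anxa8* and *Fgf18* (4 reads each over the unstimulated libraries), the lipase *Mgll* (5.84 ± 0.41), *Ifng*, the chemokine *Ccl9* (5.66 ± 0.23) and *Ckap4* (5.58 ± 0.40). The largest decreases were those of the lactate exporter *Slc16a3* (-4.68 ± 0.46), the glycogen phosphorylase *Pygl* (-4.51 ± 0.37), the desaturases *Scd1* (-4.44 ± 1.04) and *Fads2* (-4.40 ± 0.36), the corepressor *Cbfa2t3* (-4.34 ± 0.22), *Narf* (-4.19 ± 0.46), the mitophagy gene *Bnip3* (-4.14 ± 0.28) and *Ankrd37* (-4.08 ± 0.48). Of the other genes fixed for every comparison, *Il2ra* (5.39 ± 0.48), *Egr2* (4.32 ± 0.31), *Nr4a1* (2.40 ± 0.23), *Cish* (2.70 ± 0.27), *Myc* (2.02 ± 0.25), *Gzmb* (0.95 ± 0.27) and *Tbx21* (0.73 ± 0.24) were higher. *Gzma* (-1.91 ± 0.26), *Eomes* (-1.60 ± 0.24), *Mki67* (-1.71 ± 0.32) and *Ncr1* (-0.93 ± 0.26) were lower. *Prf1* (-0.12 ± 0.46, adjusted p = 0.875) and *Bcl2* (-0.35 ± 0.27, adjusted p = 0.338) did not pass the threshold.

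Of the effector cytokine list, 13 of 16 tested members were higher and 1 lower (14 and 1 adjusted over the list alone) (camera, adjusted p = 1.14e-11, and 0.0192 with estimated correlation). In the immediate early and NFAT/NF-κB list 20 of 30 tested members were higher and 1 lower (22 and 2 adjusted over the list alone) (camera, adjusted p = 2.68e-11, and 0.00978 with estimated correlation). These included the stress-induced factor *Atf3* (5.27 ± 0.30) and the lymphocyte activation factor *Irf4* (4.44 ± 0.28). Activation, costimulatory and checkpoint receptors had 10 of 19 higher and 3 lower, 11 and 3 adjusted over the list alone (camera, adjusted p = 0.00150, and 0.0487 with estimated correlation), with *Crtam* at 5.50 ± 0.18 and the hyaluronan receptor *Cd44* at 2.05 ± 0.19. Amino acid, serine and ATF4 genes had 18 of 19 higher and 0 lower, 18 and 0 adjusted over the list alone (camera, adjusted p = 1.27e-12, and 0.0142 with estimated correlation). These included *Mthfd2* (3.06 ± 0.24) and *Asns* (3.25 ± 0.27). Ribosome biogenesis genes had 21 of 24 higher and 0 lower, 22 and 0 adjusted over the list alone (camera, adjusted p = 3.31e-11, and 0.00456 with estimated correlation), for example *Nop16* (1.98 ± 0.24) and *Rrs1* (2.15 ± 0.27).

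Glycolysis, lipid synthesis and cell cycle lists fell. Glycolysis had 14 of 18 lower and 1 higher, 15 and 1 adjusted over the list alone (camera, adjusted p = 3.63e-09, and 0.0196 with estimated correlation), with triosephosphate isomerase *Tpi1* at -3.35 ± 0.22 and phosphofructokinase *Pfkl* at -3.46 ± 0.26. Cholesterol and fatty acid synthesis had 21 of 23 lower and 0 higher, 22 and 0 adjusted over the list alone (camera, adjusted p = 7.14e-12, and 0.00952 with estimated correlation), with the desaturase *Scd2* at -3.36 ± 0.20. The S phase list had 22 of 26 lower and 0 higher, 22 and 0 adjusted over the list alone (camera, adjusted p = 3.44e-12, and 9.33e-04 with estimated correlation), and *Mcm6*, a subunit of the replicative helicase, changed by -2.19 ± 0.20. The G2/M list had 24 of 26 lower and 0 higher, 25 and 0 adjusted over the list alone (camera, adjusted p = 1.08e-11, and 0.00102 with estimated correlation), and *Ccnb2* changed by -3.44 ± 0.27. Trafficking receptors and integrins had 11 of 21 lower and 1 higher, 11 and 1 adjusted over the list alone (camera, adjusted p = 5.94e-05, and 0.0483 with estimated correlation). Among them was the chemokine receptor *Cxcr3* (-4.08 ± 0.30).

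NK cell receptors and adaptors had 16 of 29 lower and 1 higher, 17 and 1 adjusted over the list alone, a call (camera, adjusted p = 3.80e-06) that was lost at adjusted p = 0.0891 with an estimated correlation. The Fc receptor *Fcgr3* (-2.88 ± 0.21) and the signalling chain *Cd247* (-2.13 ± 0.24) were among them. Quiescence-associated genes had 11 of 16 lower and 1 higher, 12 and 2 adjusted over the list alone (camera, adjusted p = 1.23e-05, and 0.0511 with estimated correlation). Interferon-stimulated genes had 8 of 30 lower and 1 higher, 8 and 1 adjusted over the list alone (camera, adjusted p = 0.0430, and 0.201 with estimated correlation), with *Irf1* at -1.93 ± 0.21. Heat shock chaperones had 5 of 11 higher and 1 lower, 5 and 1 adjusted over the list alone (camera, adjusted p = 0.0485, and 0.0891 with estimated correlation). No list of markers of other cells was called (camera, adjusted p from 0.288 to 0.976). T cell markers had 1 of 5 lower and 0 higher, 1 and 0 adjusted over the list alone and summed to 48.8 ± 4.03 CPM without and 29.0 ± 1.53 with stimulation. Macrophage, monocyte and dendritic cell markers had 2 of 18 higher and 1 lower, 2 and 1 adjusted over the list alone, with *Cd74* at 1.70 ± 0.26 and *H2-Ab1* at -1.81 ± 0.29, and summed to 92.9 ± 14.1 and 62.8 ± 6.98. B cell markers had 0 of 8 higher and 0 lower, 0 and 0 adjusted over the list alone and sums of 5.43 ± 1.5 and 2.20 ± 0.272. Without HD unstimulated replicate 2, 1235 genes were lower and *Ncr1* was no longer called (-0.61, adjusted p = 0.177), and without HD unstimulated replicate 1 the calls of *Gzmb* (0.0939), *Tbx21* (0.218), the interferon list (0.112) and the chaperone list (0.0789) were lost. *Tbx21* was also lost without HD anti-NK1.1 replicate 1 (0.0949) or 2 (0.0654), the interferon list without HD anti-NK1.1 replicate 1 (0.0777), and the chaperone list without any of 5 other libraries (0.0505 to 0.0544).

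To describe what culture itself changed, HD unstimulated libraries (n = 2) were compared with naive unstimulated libraries (n = 3). The granzyme genes *Gzmc*, *Gzmd* and *Gzme*, whose products are released to kill target cells, were far higher after culture. *Gzmc* (chromosome 14, 56231441 to 56234656, minus strand) rose from 3.66 ± 0.654 to 2114 ± 526 CPM (9.14 ± 0.22, adjusted p = 3.88e-12). *Gzmd* and *Gzme*, without a read in the naive libraries, were at least 425.8-fold and 187.8-fold higher, and these paralogs can share reads. *Gzmb* rose by 2.78 ± 0.27 and *Prf1* by 1.97 ± 0.46. The cytotoxic list as a whole was not called, with 10 of 23 higher and 6 lower, 10 and 7 adjusted over the list alone (camera, adjusted p = 0.138), a median of -0.06 and a mean of 1.59. Immediate early genes moved the other way, with *Nr4a1* at -5.13 ± 0.23 (adjusted p = 2.48e-09), and in all 1914 genes were higher and 1995 lower.

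After the granzymes, the leading increases were the glycolytic aldolase *Aldoc* (7.39 ± 0.64), *Scd1* (6.81 ± 1.04), *Dixdc1* (6.52 ± 0.50), the secreted phosphoprotein osteopontin *Spp1* (6.40 ± 0.34) and the receptor gene *Gpr141* (6.23 ± 0.37). Among the leading decreases, genes without a read in the HD libraries were *Car1*, a carbonic anhydrase of red cells (at least 215.7-fold lower), *Dtx1* (181.8-fold), *Bcl11a* (90.1-fold) and the mast cell and basophil protease *Prss34* (73.4-fold). The others were the growth factor *Csf1* (3 reads in the HD libraries), *Fosb* (-8.33 ± 0.44), the class II histocompatibility gene *H2-Aa* (-7.38 ± 0.38) and the transcription factor *Klf4* (-7.09 ± 0.22). Of the genes fixed for every comparison, *Il2ra* (2.23 ± 0.48), *Cish* (2.16 ± 0.27), *Bcl2* (1.34 ± 0.27) and *Mki67* (1.67 ± 0.32) were higher, and *Csf2* had 23 reads over the HD and 1 over the naive libraries (adjusted p = 0.00370). *Tnf* (-1.43 ± 0.31), *Ccl3* (-0.99 ± 0.29), *Ccl4* (-1.40 ± 0.28), *Ncr1* (-1.69 ± 0.26) and *Tbx21* (-2.02 ± 0.24) were lower. *Ifng* (-0.44 ± 0.26, adjusted p = 0.201), *Xcl1* (-0.71 ± 0.35, adjusted p = 0.133), *Gzma* (-0.13 ± 0.26, adjusted p = 0.729), *Egr2* (0.24 ± 0.31, adjusted p = 0.582), *Klrb1c* (-0.39 ± 0.20, adjusted p = 0.148), *Eomes* (-0.60 ± 0.24, adjusted p = 0.0734) and *Myc* (-0.13 ± 0.25, adjusted p = 0.726) did not pass the threshold.

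Proliferation and biosynthesis genes were higher. The G2/M list had 25 of 26 higher and 0 lower, 25 and 0 adjusted over the list alone (camera, adjusted p = 4.11e-17, and 4.16e-04 with estimated correlation), with the kinases *Cdk1* at 3.42 ± 0.23 and *Bub1* at 4.45 ± 0.40. The S phase list had 22 of 26 higher and 0 lower, 23 and 0 adjusted over the list alone (camera, adjusted p = 2.16e-11, and 6.85e-04 with estimated correlation). *Rrm2*, a ribonucleotide reductase subunit, stood at 2.82 ± 0.32. Cholesterol and fatty acid synthesis had 21 of 23 higher and 0 lower, 21 and 0 adjusted over the list alone (camera, adjusted p = 2.59e-16, and 0.00429 with estimated correlation). Examples were the sterol enzymes *Sqle* (5.03 ± 0.28) and *Msmo1* (4.02 ± 0.22). Glycolysis had 16 of 18 higher and 0 lower, 16 and 0 adjusted over the list alone (camera, adjusted p = 7.70e-14, and 0.00814 with estimated correlation). Examples were hexokinase *Hk2* (2.39 ± 0.19) and *Slc16a3* (5.59 ± 0.46). Ribosome biogenesis had 9 of 24 higher and 0 lower, 9 and 0 adjusted over the list alone, lost at adjusted p = 0.0512 with an estimated correlation (preset, 0.00108), with *Nop58* at 1.25 ± 0.25. The amino acid and ATF4 list had 12 of 19 higher and 3 lower, 12 and 3 adjusted over the list alone (camera, adjusted p = 0.00242, and 0.196 with estimated correlation), with *Asns* at 3.19 ± 0.27 and the transporter subunit *Slc3a2* at -1.89 ± 0.24.

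Of the immediate early and NFAT/NF-κB list, 24 of 30 tested members were lower and 1 higher (25 and 1 adjusted over the list alone) (camera, adjusted p = 8.85e-15, and 0.00469 with estimated correlation). *Tnfaip3*, an inhibitor of NF-κB, stood at -4.70 ± 0.22 and *Nfkbiz* at -5.72 ± 0.30. Quiescence-associated genes had 12 of 16 lower and 1 higher, 13 and 1 adjusted over the list alone (camera, adjusted p = 1.10e-07, and 0.0258 with estimated correlation). Trafficking receptors and integrins had 14 of 21 lower and 4 higher, 14 and 4 adjusted over the list alone (camera, adjusted p = 7.49e-05, and 0.0460 with estimated correlation), with *Cxcr4* at -5.51 ± 0.27, whereas *Cxcr6* was higher (2.89 ± 0.25). NK cell transcription factors had 11 of 22 lower and 1 higher, 12 and 1 adjusted over the list alone (camera, adjusted p = 3.66e-05, and 0.0111 with estimated correlation). NK cell receptors and adaptors had 17 of 29 lower and 2 higher, 17 and 2 adjusted over the list alone (camera, adjusted p = 2.97e-05, and 0.128 with estimated correlation). The effector cytokine list had 8 of 16 lower and 2 higher, 8 and 2 adjusted over the list alone (camera, adjusted p = 0.0420, and 0.370 with estimated correlation).

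Macrophage, monocyte and dendritic cell markers summed to 671 ± 84.3 CPM in naive and 92.9 ± 14.1 in HD cells, and their list had 14 of 18 lower and 0 higher, 15 and 0 adjusted over the list alone (camera, adjusted p = 3.56e-09, and 0.0258 with estimated correlation). *Cd74* stood at -5.96 ± 0.26 and *H2-Eb1* at -5.67 ± 0.32. Erythroid and platelet markers had 8 of 9 lower and 0 higher, 8 and 1 adjusted over the list alone (camera, adjusted p = 2.76e-08, and 0.0111 with estimated correlation), with *Hbb-bs* at least 45.4-fold and *Hba-a1* at least 62.9-fold lower. Their sum, 556 ± 194 and 675 ± 149 CPM, consisted mostly of *Car2*, singled out after its values were seen (366 ± 149 and 673 CPM). B cell markers had 5 of 8 lower and 0 higher, 7 and 0 adjusted over the list alone (camera, adjusted p = 0.0127, and 0.0920 with estimated correlation) and a sum of 16.9 ± 2.71 against 5.43 ± 1.5 CPM, with *Cd22* at least 15.1-fold lower. T cell markers had 3 of 5 lower and 0 higher, 3 and 0 adjusted over the list alone (camera, adjusted p = 0.134) and neutrophil markers 1 of 6 lower and 0 higher, 1 and 0 adjusted over the list alone (adjusted p = 0.137), without a call, and sums of 83.1 ± 5.6 against 48.8 ± 4.03 and 12.9 ± 2.07 against 5.77 ± 2.12 CPM.

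The groups lay in different pools, and with pool as a factor, estimated from the LD pair with 1 library per pool, 434 genes were higher and 572 lower; of the original calls 98.5% of those higher and 99.6% of those lower kept their direction. The calls of *Tnf* (-0.63, adjusted p = 0.514), *Ccl3* (-0.09, 0.930), *Ccl4* (-0.79, 0.345), *Prf1* (0.90, 0.536), *Ncr1* (-0.98, 0.179), *Mki67* (1.15, 0.262), *Slc3a2* (-1.41, 0.0565), *Il2ra* (2.07, 0.192), *Bcl2* (1.66, 0.0546), *Nop58* (1.40, 0.0844) and *Csf2* (2.69, 0.302) were then lost, as were those of the effector (0.414), ribosome (0.245) and B cell (0.119) lists. Without pool as a factor, the counts were 1100 and 1317 without HD unstimulated replicate 1, where *Prf1* (adjusted p = 0.0530) was lost, and 1264 genes were higher without replicate 2; *Ccl3* was lost without either (0.0598 and 0.101) or without naive replicate 6 (0.0592), and the effector list without naive unstimulated replicate 4 (0.0763) or 6 (0.0634) or naive anti-NK1.1 replicate 5 (0.0554).

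Stimulated cells were compared next, with HD anti-NK1.1 (n = 3) against naive anti-NK1.1 libraries (n = 3). *Ifng* was higher in HD cells by 4.06 ± 0.23 (adjusted p = 1.85e-08), *Tnf* by 3.10 ± 0.28, *Xcl1* by 2.79 ± 0.31, *Ccl3* by 2.07 ± 0.26 and *Ccl4* by 1.16 ± 0.25. *Gzmb* stood at 2905 ± 138 against 199 ± 43.2 CPM (3.89 ± 0.24, adjusted p = 3.15e-08), and *Prf1* was higher by 2.96 ± 0.41. *Gzmc* reached 4033 ± 316 CPM (11.01 ± 0.20). *Eomes* was lower (-3.12 ± 0.22, adjusted p = 1.12e-07), and *Tbx21* was not called (0.00 ± 0.21, adjusted p = 0.991). Here 2439 genes were higher and 2584 lower.

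*Gzmd*, without a read in the naive libraries, was at least 1245.6-fold higher, and *Gzme* had 2 reads there (adjusted p = 2.10e-08). The next largest increases were the growth factor *Hbegf* (6.88 ± 0.39), *Spp1* (6.78 ± 0.30), *Ccl1* (6.13 ± 0.22), the transcriptional repressor *Zbtb32* (5.84 ± 0.49) and the glycosyltransferase *Galnt3* (5.51 ± 0.53). The largest decreases were those of *Cxcl9* (-7.30 ± 0.54), the chemokine receptors *Cxcr4* (-6.38 ± 0.24) and *Ccr7* (-5.73 ± 0.34), the small GTPase *Arl4d* (-6.13 ± 0.28), *H2-Aa* (-5.93 ± 0.34), the cytokine receptor chain *Csf2rb* (-5.37 ± 0.35), the interferon-induced GTPase *Iigp1* (-4.97 ± 0.43) and *Phactr3* (-4.93 ± 0.35). *Csf2* (5.06 ± 0.71), *Il2ra* (3.73 ± 0.43), *Myc* (2.38 ± 0.22), *Cish* (2.45 ± 0.24) and *Mki67* (1.17 ± 0.29) were higher, and *Nr4a1* (-2.47 ± 0.21) and *Klrb1c* (-0.88 ± 0.18) lower. *Gzma* (-0.53 ± 0.23, adjusted p = 0.0810), *Egr2* (-0.14 ± 0.28, adjusted p = 0.717), *Ncr1* (0.18 ± 0.23, adjusted p = 0.548) and *Bcl2* (0.44 ± 0.24, adjusted p = 0.155) did not pass the threshold.

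Of the effector cytokine list, 13 of 16 tested members were higher and 3 lower (13 and 3 adjusted over the list alone) (camera, adjusted p = 7.83e-06, and 0.0728 with estimated correlation). *Lta*, the gene of lymphotoxin-α, stood at 4.95 ± 0.34. The cytotoxic list had 13 of 23 higher and 3 lower, 13 and 3 adjusted over the list alone (camera, adjusted p = 3.04e-04, and 0.0611 with estimated correlation). Both cell cycle lists were higher in HD cells. The G2/M list had 24 of 26 higher and 0 lower, 24 and 0 adjusted over the list alone (camera, adjusted p = 1.75e-11, and 0.00179 with estimated correlation). For S phase 15 of 26 tested members were higher and 3 lower (15 and 4 adjusted over the list alone) (camera, adjusted p = 0.00118, and 0.0146 with estimated correlation). *Ccnb1* stood at 3.54 ± 0.37, while *Mcm6* was lower (-2.57 ± 0.18). Ribosome biogenesis had 18 of 24 higher and 0 lower, 20 and 0 adjusted over the list alone (camera, adjusted p = 1.34e-08, and 0.0105 with estimated correlation). *Dkc1* stood at 1.65 ± 0.18. Glycolysis had 10 of 18 higher and 2 lower, 10 and 2 adjusted over the list alone (camera, adjusted p = 0.00721, and 0.170 with estimated correlation). Cholesterol and fatty acid synthesis had 12 of 23 higher and 1 lower, 12 and 1 adjusted over the list alone (camera, adjusted p = 0.00905, and 0.166 with estimated correlation). Heat shock chaperones had 6 of 11 higher and 0 lower, 6 and 1 adjusted over the list alone (camera, adjusted p = 0.00905, and 0.0538 with estimated correlation).

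NK cell transcription factors were lower in HD cells, with 17 of 22 lower and 1 higher, 17 and 1 adjusted over the list alone (camera, adjusted p = 6.91e-08, and 0.00713 with estimated correlation). These included *Klf2* (-3.89 ± 0.18) and *Tcf7* (-3.66 ± 0.20). Trafficking genes had 16 of 21 lower and 0 higher, 16 and 0 adjusted over the list alone (camera, adjusted p = 8.11e-09, and 0.0109 with estimated correlation). Quiescence-associated genes had 14 of 16 lower and 0 higher, 14 and 0 adjusted over the list alone (camera, adjusted p = 2.81e-10, and 0.0118 with estimated correlation). Cytokine receptors and STATs had 13 of 21 lower and 3 higher, 13 and 3 adjusted over the list alone (camera, adjusted p = 2.04e-04, and 0.0109 with estimated correlation), with the interleukin-7 receptor *Il7r* at -4.44 ± 0.24 and *Stat4*, which transmits interleukin-12 signals, at -3.18 ± 0.26. NK cell receptors had 14 of 29 lower and 2 higher, 15 and 2 adjusted over the list alone (camera, adjusted p = 0.00978, and 0.295 with estimated correlation). Interferon-stimulated genes had 12 of 30 lower and 2 higher, 12 and 2 adjusted over the list alone (camera, adjusted p = 0.00731, and 0.134 with estimated correlation). Macrophage, monocyte and dendritic cell markers summed to 602 ± 95 CPM in naive and 62.8 ± 6.98 in HD cells, with 9 of 18 lower and 0 higher, 9 and 0 adjusted over the list alone (camera, adjusted p = 3.62e-06, and 0.0611 with estimated correlation), and *Siglech* of plasmacytoid dendritic cells was at least 35.0-fold lower. Erythroid and platelet markers had 8 of 9 lower and 0 higher, 8 and 0 adjusted over the list alone (camera, adjusted p = 1.34e-08, and 0.0109 with estimated correlation), with *Ppbp* at least 61.9-fold lower. T cell markers had 3 of 5 lower and 1 higher, 3 and 1 adjusted over the list alone (camera, adjusted p = 0.282) and neutrophil markers 3 of 6 lower and 0 higher, 3 and 0 adjusted over the list alone (adjusted p = 0.0839), without a call, and sums of 43.2 ± 5.34 against 29.0 ± 1.53 and 10.5 ± 3.78 against 5.03 ± 0.280 CPM. The groups were in different pools, and with pool as a factor 489 genes were higher and 618 lower, with 97.6% and 98.7% of the original calls keeping their direction. The calls of *Csf2* (4.27, adjusted p = 0.0834), *Prf1* (1.89, 0.143), *Klrb1c* (-0.75, 0.197), *Mki67* (0.65, 0.512), the NK cell receptors (0.126) and the chaperones (0.119) were then lost, and *Egr2* was called lower (-1.42, 0.0395). The immediate early list was not called, with 12 of 30 lower and 5 higher, 13 and 5 adjusted over the list alone (camera, adjusted p = 0.109).

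LD cells were compared with naive cells after anti-NK1.1 (n = 2 and n = 3). *Gzmc* rose to 120 ± 12.1 CPM in LD cells from 1.89 ± 0.237 (5.94 ± 0.22, adjusted p = 1.72e-09) and *Ccl1* to 3542 ± 41.7 from 110 ± 29.2 (5.05 ± 0.25). *Gzmb* was higher by 1.71 ± 0.27, *Xcl1* by 1.96 ± 0.35, *Tnf* by 1.58 ± 0.31 and *Ifng* by 1.20 ± 0.26 (adjusted p = 0.00750). *Gzma* (-1.76 ± 0.26, adjusted p = 6.64e-04) and *Eomes* (-1.59 ± 0.24) were lower. In all, 758 genes were higher and 808 lower.

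Other leading increases were those of the troponin gene *Tnni1* (4.0 ± 0.42), the mitotic spindle protein *Nusap1* (3.92 ± 0.49), *Mgll* (3.86 ± 0.41), the tumor necrosis factor family ligand *Tnfsf8* (3.34 ± 0.46), the growth factor *Pdgfa* (3.01 ± 0.30) and the deubiquitinase *Usp2* (2.96 ± 0.29). The leading decreases were the mast cell chymase *Cma1* (-6.04 ± 0.26), *Ly6a*, the gene of Sca-1 (-4.53 ± 0.34), *H2-Aa* (-3.35 ± 0.38) and *H2-Ab1* (-3.26 ± 0.29), *Cbfa2t3* (-3.31 ± 0.22), the transcription factor *Myb* (-3.14 ± 0.40), *Cxcl9* (-3.14 ± 0.60) and *Gbp2* (-3.08 ± 0.25). *Il2ra* (2.43 ± 0.48), *Cish* (1.96 ± 0.27), *Myc* (1.78 ± 0.25), *Egr2* (1.13 ± 0.31), *Klrb1c* (1.30 ± 0.20) and *Ncr1* (1.11 ± 0.26) were higher, and *Nr4a1* (-0.77 ± 0.23) was lower. *Csf2* (2.36 ± 0.79, adjusted p = 0.0611), *Ccl3* (0.45 ± 0.29, adjusted p = 0.335), *Ccl4* (0.71 ± 0.28, adjusted p = 0.102), *Prf1* (1.23 ± 0.46, adjusted p = 0.0887), *Tbx21* (-0.23 ± 0.24, adjusted p = 0.581), *Bcl2* (0.51 ± 0.27, adjusted p = 0.230) and *Mki67* (0.92 ± 0.32, adjusted p = 0.0750) did not pass the threshold.

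The G2/M list had 18 of 26 higher and 0 lower, 23 and 0 adjusted over the list alone (camera, adjusted p = 1.12e-17, and 3.69e-04 with estimated correlation). Of the S phase list, 12 of 26 tested members were higher and 1 lower (14 and 2 adjusted over the list alone) (camera, adjusted p = 9.05e-06, and 0.00635 with estimated correlation). *Ccna2* stood at 2.95 ± 0.27 and *Rrm2* at 2.54 ± 0.32. Of the ribosome biogenesis list, 16 of 24 tested members were higher and 0 lower (21 and 0 adjusted over the list alone) (camera, adjusted p = 1.61e-10, and 0.00635 with estimated correlation). *Dkc1* stood at 1.28 ± 0.20. Effector cytokines had 9 of 16 higher and 1 lower, 13 and 2 adjusted over the list alone (camera, adjusted p = 2.42e-08, and 0.0351 with estimated correlation). *Lta* stood at 4.23 ± 0.38 and *Ccl9* at 2.45 ± 0.23. Heat shock chaperones had 6 of 11 higher and 0 lower, 6 and 0 adjusted over the list alone (camera, adjusted p = 2.51e-04, and 0.0157 with estimated correlation). The cytotoxic list had 5 of 23 higher and 2 lower, 8 and 3 adjusted over the list alone (camera, adjusted p = 0.0337, and 0.226 with estimated correlation). Oxidative phosphorylation had 3 of 44 higher and 0 lower, 2 and 0 adjusted over the list alone (camera, adjusted p = 9.89e-05, and 0.374 with estimated correlation). In cholesterol and fatty acid synthesis, 4 of 23 tested members were higher and 1 lower (9 and 2 adjusted over the list alone) (camera, adjusted p = 0.00975, and 0.188 with estimated correlation). *Cycs*, the gene of cytochrome c, stood at 1.41 ± 0.27 and *Sqle* at 1.74 ± 0.28.

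Quiescence-associated genes had 10 of 16 lower and 0 higher, 11 and 0 adjusted over the list alone (camera, adjusted p = 2.74e-08, and 0.0238 with estimated correlation). NK cell transcription factors had 7 of 22 lower and 0 higher, 10 and 0 adjusted over the list alone (camera, adjusted p = 1.41e-05, and 0.0130 with estimated correlation). Cytokine receptors and STATs had 7 of 21 lower and 2 higher, 9 and 2 adjusted over the list alone (camera, adjusted p = 3.32e-04, and 0.0157 with estimated correlation). Trafficking genes had 8 of 21 lower and 0 higher, 9 and 1 adjusted over the list alone (camera, adjusted p = 3.47e-05, and 0.0364 with estimated correlation). *Cxcr4* stood at -2.81 ± 0.27. Interferon-stimulated genes had 7 of 30 lower and 0 higher, 8 and 0 adjusted over the list alone (camera, adjusted p = 1.94e-04, and 0.0482 with estimated correlation). Macrophage, monocyte and dendritic cell markers had 7 of 18 lower and 0 higher, 8 and 0 adjusted over the list alone (camera, adjusted p = 2.51e-06, and 0.0482 with estimated correlation) and a sum of 127 ± 38.6 CPM against 602 ± 95, with *Cd74* at -2.70 ± 0.26. Erythroid and platelet markers had 5 of 9 lower and 0 higher, 5 and 1 adjusted over the list alone (camera, adjusted p = 3.93e-06, and 0.0238 with estimated correlation), and *Hbb-bs* had 2 reads over the LD and 612 over the naive libraries. T cell markers had 3 of 5 lower and 0 higher, 3 and 0 adjusted over the list alone (camera, adjusted p = 0.0163, and 0.0576 with estimated correlation) and a sum of 21.1 ± 2.44 against 43.2 ± 5.34. Neutrophil markers, without a camera call (0.260), summed to 23.0 ± 6.56 CPM in LD and 10.5 ± 3.78 in naive cells.

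Within pool 2, without LD replicate 1, the counts were 313 and 347, with *Egr2* (0.49, adjusted p = 0.339), *Nr4a1* (-0.50, 0.311) and the cytotoxic list (0.0672) lost; without LD replicate 3 they were 392 and 427, with *Ifng* (0.78, 0.104), *Tnf* (1.18, 0.0720), *Ncr1* (0.76, 0.145) and oxidative phosphorylation (0.0838) lost and *Egr2* at 1.77, and the lone LD library is assumed to vary like the other groups. Without naive replicate 5 the counts were 497 and 529, and leaving out a naive library also ended the calls of *Egr2* (0.0542 to 0.0677 over the 3 libraries), *Nr4a1* (replicates 1 and 5, 0.109 for both) and the cytotoxic list (replicates 1 and 4, 0.0601 and 0.0566).

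The IL-15 conditions were compared directly after anti-NK1.1, with 3 HD and 2 LD libraries. *Ifng* was higher in HD cells, at 3349 ± 315 against 480 ± 194 CPM (2.86 ± 0.26, adjusted p = 7.82e-06). *Gzmc* was higher by 5.07 ± 0.22 (adjusted p = 1.54e-08), *Gzmb* by 2.17 ± 0.27 and *Ccl3* by 1.63 ± 0.29. *Klrb1c* was lower in HD cells (-2.18 ± 0.20, adjusted p = 9.18e-06), as were *Eomes* (-1.53 ± 0.24) and the T cell factor gene *Tcf7* (-3.05 ± 0.22). In all, 378 genes were higher and 615 lower.

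*Gzmd* (7.74 and 11.36 without LD replicate 3 or 1) and *Gzme* (7.89 and 10.56) were higher, with 26 and 13 reads in LD replicate 1 and none in LD replicate 3, so the sizes stay open. Other leading increases were the actin regulator *Avil* (4.60 ± 0.62, 5.47 and 3.74 without LD replicate 3 or 1), *Gpr141* (4.44 ± 0.37), *Spp1* (4.24 ± 0.34) and the metallothioneins *Mt2* (4.14 ± 0.32) and *Mt1* (4.04 ± 0.29). The leading decreases included those of platelet factor *Pf4* (-6.13 ± 0.44), *Phactr3* (-5.09 ± 0.39), *Arl4d* (-4.27 ± 0.31), *Tcf7*, *Ypel3* (-2.86 ± 0.30), *Klf3* (-2.50 ± 0.32) and *Cd7* (-2.48 ± 0.26). *Tnf* (1.52 ± 0.31), *Csf2* (2.70 ± 0.79), *Gzma* (1.23 ± 0.26) and *Prf1* (1.73 ± 0.46) were higher, and *Nr4a1* (-1.70 ± 0.23), *Egr2* (-1.27 ± 0.31) and *Ncr1* (-0.92 ± 0.26) lower. *Ccl4* (0.45 ± 0.28, adjusted p = 0.365), *Xcl1* (0.84 ± 0.35, adjusted p = 0.166), *Il2ra* (1.30 ± 0.48, adjusted p = 0.116) and *Tbx21* (0.23 ± 0.24, adjusted p = 0.625) did not pass the threshold. *Myc* (0.60 ± 0.25, adjusted p = 0.161), *Cish* (0.49 ± 0.27, adjusted p = 0.308), *Bcl2* (-0.07 ± 0.27, adjusted p = 0.916) and *Mki67* (0.25 ± 0.32, adjusted p = 0.715) also did not pass it.

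The cytotoxic list had 11 of 23 higher and 2 lower, 11 and 3 adjusted over the list alone (camera, adjusted p = 3.59e-07, and 0.0254 with estimated correlation), and *Gzmg*, without a read in LD cells, was at least 114.1-fold higher. Trafficking genes had 10 of 21 lower and 0 higher, 10 and 0 adjusted over the list alone (camera, adjusted p = 3.27e-10, and 0.0179 with estimated correlation). *Cxcr4* stood at -3.57 ± 0.27 and *Cxcr3* at -3.66 ± 0.30. Quiescence-associated genes had 10 of 16 lower and 0 higher, 11 and 0 adjusted over the list alone (camera, adjusted p = 3.27e-10, and 0.0254 with estimated correlation). *Klf2* stood at -2.49 ± 0.20 and *Il7r* at -2.89 ± 0.27. NK cell transcription factors had 9 of 22 lower and 1 higher, 12 and 1 adjusted over the list alone (camera, adjusted p = 3.94e-07, and 0.0179 with estimated correlation). Cytokine receptors and STATs had 8 of 21 lower and 1 higher, 9 and 2 adjusted over the list alone (camera, adjusted p = 8.95e-04, and 0.0254 with estimated correlation).

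The calls of 9 further lists were lost with an estimated correlation. NK cell receptors had 11 of 29 lower and 1 higher, 16 and 1 adjusted over the list alone (camera, adjusted p = 3.41e-08, and 0.0688 with estimated correlation), with *Klrb1b* at -2.22 ± 0.24. Immediate early genes had 8 of 30 lower and 2 higher, 12 and 2 adjusted over the list alone (camera, adjusted p = 0.00681, and 0.155 with estimated correlation). Effector cytokines had 5 of 16 higher and 3 lower, 7 and 3 adjusted over the list alone (camera, adjusted p = 0.0190, and 0.316 with estimated correlation). Glycolysis had 6 of 18 higher and 1 lower, 8 and 2 adjusted over the list alone (camera, adjusted p = 0.00165, and 0.142 with estimated correlation). Ribosome biogenesis was called as higher, with a median of 0.37, but had 0 of 24 higher and 0 lower, 0 and 0 adjusted over the list alone (camera, adjusted p = 0.0190, and 0.140 with estimated correlation). ILC1-associated genes had 3 of 12 lower and 0 higher, 3 and 0 adjusted over the list alone (camera, adjusted p = 0.0476, and 0.133 with estimated correlation). Macrophage, monocyte and dendritic cell markers had 5 of 18 lower and 0 higher, 6 and 0 adjusted over the list alone (camera, adjusted p = 3.81e-04, and 0.140 with estimated correlation), with *H2-Aa* at -2.59 ± 0.38, and summed to 62.8 ± 6.98 against 127 ± 38.6 CPM. Neutrophil markers had 1 of 6 lower and 0 higher, 4 and 0 adjusted over the list alone (camera, adjusted p = 0.00137, and 0.0573 with estimated correlation), with *Mpo* at least 34.9-fold lower. Erythroid and platelet markers had 3 of 9 lower and 0 higher, 3 and 0 adjusted over the list alone (camera, adjusted p = 2.16e-04, and 0.0686 with estimated correlation), with *Ppbp* at least 46.5-fold lower. T cell markers had 1 of 5 higher and 0 lower, 1 and 1 adjusted over the list alone, without a call (adjusted p = 0.490), and summed to 29.0 ± 1.53 against 21.1 ± 2.44 CPM. S phase genes (2 of 26 lower and 1 higher, 2 and 1 adjusted over the list alone, camera, adjusted p = 0.781) and G2/M genes (1 of 26 higher and 0 lower, 0 and 0 adjusted over the list alone, adjusted p = 0.0658) were not called.

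Within pool 1, without LD replicate 3, the counts were 135 and 309, with *Prf1* (1.20, adjusted p = 0.299), *Ncr1* (-0.57, 0.360), *Csf2* (2.30, 0.286), the ribosome list (0.438) and the ILC1 list (0.0953) lost and *Egr2* at -1.91; without LD replicate 1 they were 198 and 406, with *Tnf* (1.12, 0.104), *Gzma* (0.95, 0.106), *Egr2* (-0.62, 0.241), *Csf2* (3.10, 0.111) and the effector list (0.222) lost. Without HD anti-NK1.1 replicate 1, 2 or 3, 205, 222 and 230 genes were higher, and the calls of *Csf2* (0.0697 to 0.166), *Prf1* (0.0542 to 0.0899) and *Ncr1* (0.0567 to 0.110) were each lost, as were *Egr2* without replicate 1 (0.0655) or 2 (0.0686), the ribosome list without replicate 3 (0.0687) and the ILC1 list in 6 further omissions (0.0518 to 0.0637).

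HD and naive responses to anti-NK1.1 were compared by their difference, HD (3 and 2 libraries) minus naive (3 and 3). Because each response was measured within 1 pool, an additive pool effect cancels in this difference. The response of *Ifng* was larger in HD cells by 4.50 ± 0.34 on the log2 scale (adjusted p = 1.35e-06) and that of *Tnf* by 4.54 ± 0.42. *Xcl1* (3.50 ± 0.47), *Ccl3* (3.06 ± 0.38) and *Ccl4* (2.56 ± 0.37) also differed in this direction. *Eomes* differed the other way (-2.52 ± 0.33, adjusted p = 1.74e-04), since it rose in naive and fell in HD cells. In all, 833 genes had a more positive and 925 a more negative response in HD cells.

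**Figure D3:**
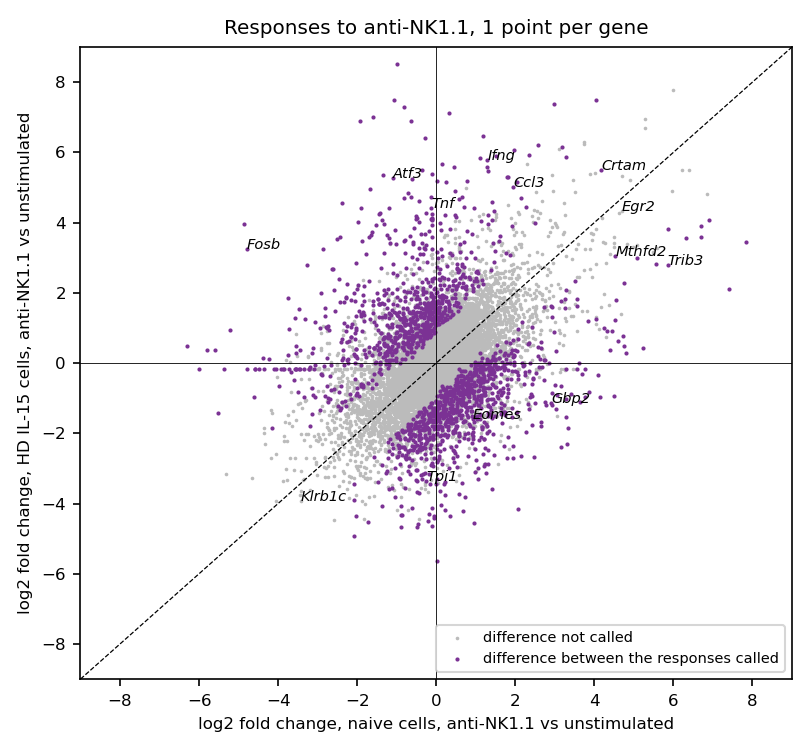
Log2 fold change after anti-NK1.1 in naive cells (x axis) and in HD IL-15 cells (y axis), 1 point per tested gene, with the genes whose responses differed by the limma test in purple and the line of equal responses dashed. *Ifng*, *Tnf* and *Atf3* lie far above the line, *Tpi1* and *Gbp2* below it; a flat streak just under 0 holds genes without reads in the HD libraries.

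Leading positive differences were those of *Fosb* (8.03 ± 0.59), cyclin D1 *Ccnd1* (6.64 ± 0.40), *Atf3* (6.36 ± 0.40), the kinase *Plk3* (5.71 ± 0.34) and *Nfkbiz* (5.62 ± 0.41). *Fosb* and *Nfkbiz* fell in naive and rose in HD cells. For *Bcl11a*, *Dtx1* and *Csf1*, also among the 8 leading genes, the size depends on the offset, as HD unstimulated libraries held 0, 0 and 3 reads. Leading negative differences were those of *Cables1* (-5.64 ± 0.43), *Ly6a* (-5.43 ± 0.45), *Dixdc1* (-4.81 ± 0.67), *Mxi1* (-4.54 ± 0.68), the integrin *Itgb3* (-4.44 ± 0.37), *Narf* (-4.42 ± 0.61) and *Fads2* (-4.35 ± 0.49), besides *Slc1a4*, with 3 reads in naive unstimulated cells. Of the fixed genes, *Gzmb* (1.11 ± 0.36, adjusted p = 0.0499), *Nr4a1* (2.66 ± 0.31), *Ncr1* (1.87 ± 0.35), *Tbx21* (2.03 ± 0.32) and *Myc* (2.51 ± 0.33) had a more positive response in HD cells. *Ncr1* fell less there, and *Tbx21* fell in naive but rose in HD cells. No call was made for *Gzma* (-0.39 ± 0.35, adjusted p = 0.490), *Prf1* (0.99 ± 0.61, adjusted p = 0.308), *Egr2* (-0.38 ± 0.41, adjusted p = 0.588), *Il2ra* (1.5 ± 0.64, adjusted p = 0.135) or *Klrb1c* (-0.49 ± 0.27, adjusted p = 0.237). No call was made either for *Cish* (0.29 ± 0.36, adjusted p = 0.647), *Bcl2* (-0.90 ± 0.36, adjusted p = 0.107), *Mki67* (-0.51 ± 0.44, adjusted p = 0.478) and *Csf2* (adjusted p = 0.349), whose value rests on 1 read in naive unstimulated cells.

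Of the effector cytokine list, 11 of 16 tested members were higher and 1 lower (12 and 1 adjusted over the list alone) (camera, adjusted p = 2.07e-11, and 0.0226 with estimated correlation). In the immediate early and NFAT/NF-κB list 21 of 30 tested members were higher and 1 lower (22 and 1 adjusted over the list alone) (camera, adjusted p = 1.12e-13, and 0.0120 with estimated correlation). The list summed to 3994 and 4341 CPM in HD unstimulated, 8015 to 10437 in HD anti-NK1.1, 15935 to 18768 in naive unstimulated and 12726 to 16234 in naive anti-NK1.1 libraries. Heat shock chaperones had 5 of 11 higher and 0 lower, 8 and 0 adjusted over the list alone (camera, adjusted p = 1.91e-04, and 0.0138 with estimated correlation), with *Hspa5* at 2.49 ± 0.38. Ribosome biogenesis had 2 of 24 higher and 0 lower, 2 and 0 adjusted over the list alone (camera, adjusted p = 9.98e-04, and 0.0499 with estimated correlation). The cytotoxic list had 8 of 23 higher and 1 lower, 8 and 1 adjusted over the list alone (camera, adjusted p = 4.31e-04, and 0.0614 with estimated correlation). *Nkg7* stood at 2.10 ± 0.30 and *Gzmc* at 1.87 ± 0.30.

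Cholesterol and fatty acid synthesis had 16 of 23 lower and 0 higher, 18 and 0 adjusted over the list alone (camera, adjusted p = 1.63e-13, and 0.0120 with estimated correlation). Glycolysis had 14 of 18 lower and 1 higher, 14 and 1 adjusted over the list alone (camera, adjusted p = 9.42e-08, and 0.0292 with estimated correlation). *Tpi1* stood at -3.09 ± 0.30 and *Pkm* at -2.24 ± 0.30. The S phase list had 7 of 26 lower and 0 higher, 7 and 0 adjusted over the list alone (camera, adjusted p = 4.31e-04, and 0.0138 with estimated correlation), with *Mcm6* at -3.28 ± 0.27. The G2/M list had 4 of 26 lower and 0 higher, 5 and 0 adjusted over the list alone (camera, adjusted p = 0.00279, and 0.0292 with estimated correlation). Cytokine receptors and STATs had 7 of 21 lower and 1 higher, 12 and 1 adjusted over the list alone (camera, adjusted p = 3.81e-04, and 0.0138 with estimated correlation). *Il10ra* stood at -3.91 ± 0.34 and *Stat4* at -3.06 ± 0.39. ILC1-associated genes, shared with a related innate lymphocyte of tissues, had 5 of 12 lower and 0 higher, 5 and 0 adjusted over the list alone (camera, adjusted p = 0.00369, and 0.0292 with estimated correlation). Trafficking genes had 7 of 21 lower and 2 higher, 9 and 4 adjusted over the list alone (camera, adjusted p = 0.0259, and 0.203 with estimated correlation).

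Across all tested genes the responses correlated with Pearson r = 0.40 and Spearman rho = 0.40, and the compared libraries were not shared; genes are not independent replicates. Of the called genes, 681 rose and 788 fell in both cell states, where independent lists would share 267 and 293, and 221 moved in opposite directions, where 559 would. The call of *Gzmb* was lost without any one of 9 libraries (adjusted p from 0.0702 to 0.157), and that of the trafficking list without HD unstimulated replicate 2 (0.0681).

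**Figure D4:**
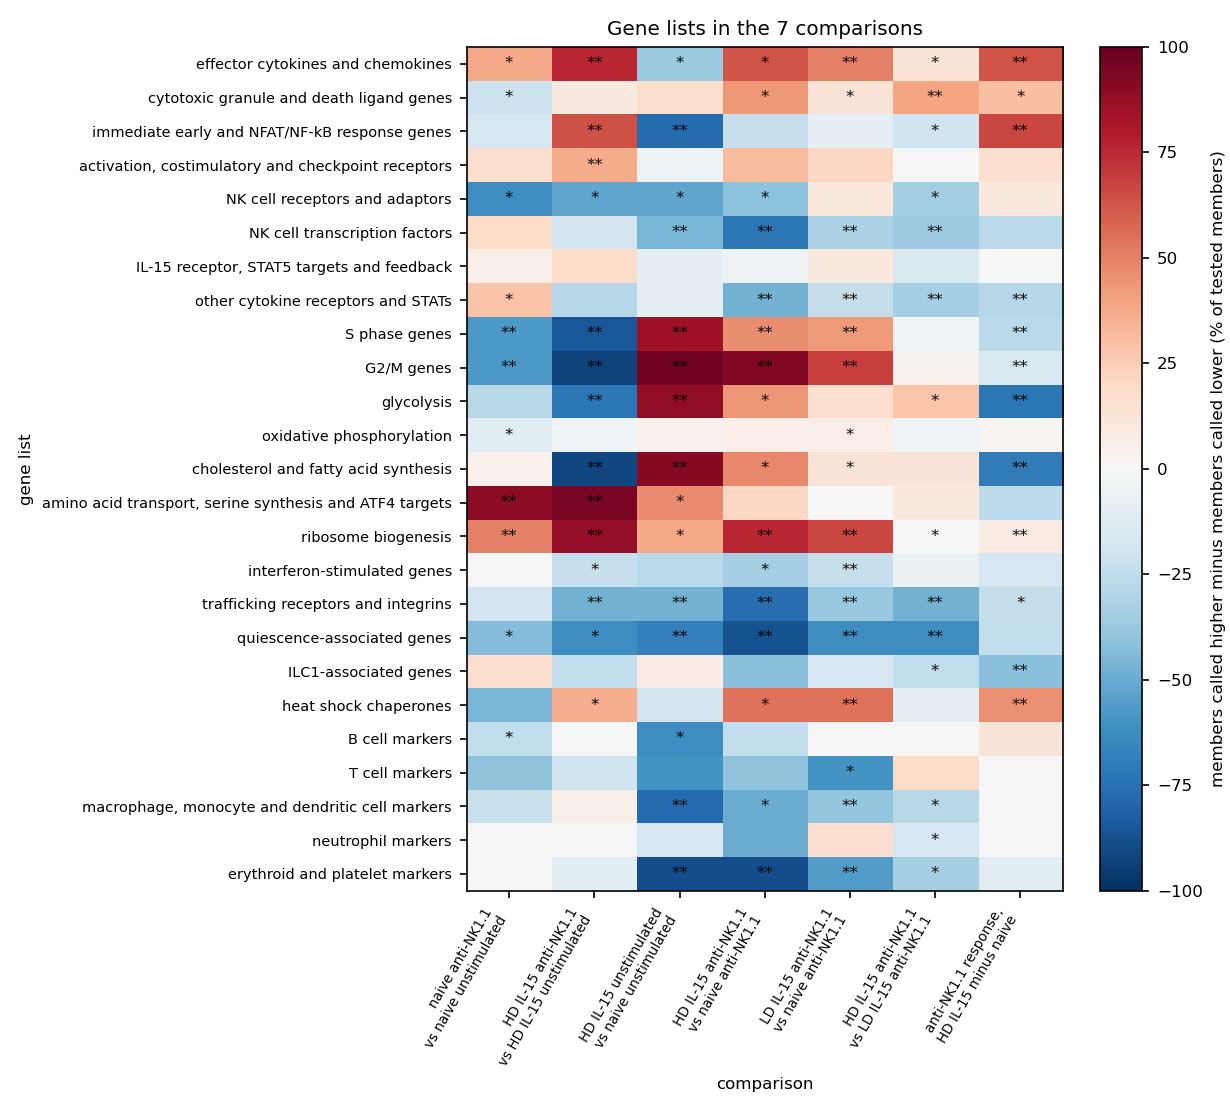
Gene lists (y axis) in the 7 comparisons (x axis), coloured by the percentage of tested members called higher minus the percentage called lower. One asterisk marks a camera call at an adjusted p under 0.05 with the preset correlation of 0.01, and a pair of them marks a call that also held with an estimated correlation, which was so for 59 of 98 calls.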

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

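The test of the immediate early genes against phagocyte markers was chosen only after the result was seen. The responses to anti-NK1.1 drew a closer look because the test of their difference, HD minus naive, passed its threshold for 833 genes upward and 925 downward. Groups of 2 or 3 libraries were too small to test for outlying samples, and every deposited library entered the comparisons.

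List medians of this difference were 3.27 for effector cytokines, 2.02 for immediate early genes, 0.88 for heat shock chaperones and 0.74 for ribosome biogenesis. They were -2.47 for cholesterol and fatty acid synthesis, -1.48 for glycolysis, -1.19 for other cytokine receptors and STATs, -0.80 for G2/M, -0.69 for S phase and -0.59 for ILC1-associated genes. Among the fixed genes the difference was 4.50 for *Ifng*, 4.54 for *Tnf*, 3.50 for *Xcl1*, 3.06 for *Ccl3*, 2.56 for *Ccl4*, 2.66 for *Nr4a1*, 2.51 for *Myc*, 2.03 for *Tbx21*, 1.87 for *Ncr1*, 1.11 for *Gzmb* and -2.52 for *Eomes*. The call of *Gzmb* was lost without any one of 9 libraries (adjusted p up to 0.157).

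HD and naive libraries lay in different pools, so pool was weighed as a source of the genes called between them. If pool were the whole cause, LD replicate 1 minus 3, which differ in pool, would follow HD minus naive with a slope near 1. The slope over the called genes was 0.033 without stimulation (95% interval over genes only, 0.022 to 0.045) and 0.043 with anti-NK1.1 (0.029 to 0.055). Pairs of libraries from 1 pool gave slopes of -0.018 to 0.021 and -0.003 to 0.02, so a small pool effect stays open, and 1 LD library per pool cannot bound it for single genes. The authors' quantile normalization could also shift calls, yet among the 4659 genes with recoverable reads 92.2% and 93.7% of calls were made again, in the same direction, from reads scaled by size factors, and higher-expressed genes were not covered. With anti-NK1.1 the real split called 5023 genes and the highest of the other splits 0, but 10 splits (1 as large, the real one) cannot give a share under 0.05, and what culture did to the cells stays open beside these.

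The same limit of 10 splits holds for the naive response, where 1 split, the real one, called 3376 genes and the highest other 1.

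Immediate early genes were higher in naive than in HD unstimulated libraries, with a list median of -2.31 for HD minus naive. RNA of macrophages, monocytes or dendritic cells in the naive libraries stays open: the 30 members lost 22.38 to 24.39 times the summed level that the 18 markers of those cells lost, but how far those cells express the members was not measured. Pool is argued against by the LD pair, whose median over members was -0.05 (-0.22 to 0.08 over genes). The labels do not say how naive cells were handled before lysis, so a response to isolation may contribute to the list's level; neither this nor a change brought by culture itself was tested.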

How the results depend on the processing

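Chosen after the data were seen were no variance trend, the offset of 8, pool, median-ratio scaling and both tests of recovered reads. All 14 counts of calls stayed within 1.5 times under median-ratio scaling, no filter, no variance trend, the offset and robust moderation, where at most 7 of 348 named results changed their call. Median-ratio scaling moved the median gene by at most 0.027, small by construction after quantile normalization and so no test of scaling. Recovered reads moved it by -0.134 (HD against naive, unstimulated) and -0.118 (stimulated). Unread genes limit the depth: folds near 3 reads are bounds, and recovered reads covered 4659 genes, of whose calls 81.9% to 100% were kept, and 66.4% to 99.1% with limma-voom. With limma-voom, LD against naive gave 292 higher and 406 lower (166 and 232 as deposited) and HD against LD 388 and 252 (150 and 161); the cause was not tested. Beyond recovered reads, alternatives that need counts (other size factors, library totals, count-model tests) were not run.

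Counts follow as higher and lower for the naive response, the HD response, HD against naive unstimulated and stimulated, LD against naive, HD against LD, and the difference between responses. With the filter of 20 CPM, which tested 5475 genes, they were 937 and 884, 1043 and 1115, 888 and 921, 1194 and 1350, 447 and 472, 172 and 353, and 446 and 550. Against a fold change of 1.5, a stricter hypothesis by construction, they were 560 and 549, 826 and 856, 794 and 943, 1017 and 1226, 162 and 195, 99 and 202, and 337 and 324, and 27 named results lost their call. With the compared groups alone, so fewer samples, LD against naive gave 387 and 518 and HD against LD 403 lower. An estimated correlation kept 59 of 98 list calls; fry made 137 calls.

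Replicate pairing stays open: deviations in groups of 2 mirror each other. They correlated at -0.143 to 0.162 in 13 same-numbered pairs and -0.162 to 0.172 in others. With the replicate block counts were 962 and 902 (naive response), 1003 and 1039, 1086 and 1210, 114 and 111, 238 and 339, and 429 and 427, with the HD response within 1.5 times; the block costs degrees of freedom. Of the named results 27 lost their call, and 94 of 98 list calls were kept. Of uncalled genes under the block, *Prf1* (HD response) went to 0.074, *Egr2* and *Tbx21* (HD against naive, stimulated) to 0.21 and -0.157, and *Bcl2* (HD against LD) to 0.055.

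With pool as a factor, estimated from 1 LD library per pool, counts were 434 and 572 (HD against naive unstimulated), 489 and 618 (stimulated), 313 and 345 (LD against naive) and 135 and 309 (HD against LD), as the median standard error rose, for example from 0.334 to 0.611 in the first. Of the called genes there, 417 and 524 were called again. Of the list calls 90 of 98 were kept, and of 348 named results 318 kept their call, 20 lost it and 2 gained it (*Prf1* in the naive response and *Egr2* in HD against naive stimulated). The other 8, all uncalled, reversed: *Ifng* (0.408), *Gzma* (0.428), *Egr2* (-1.043) and *Myc* (0.618) in HD against naive unstimulated, *Gzma* (0.035) stimulated, *Tbx21* (0.092) in LD against naive, and *Bcl2* (0.089) and *Mki67* (-0.014) in HD against LD; the cause was not tested.

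Without 1 library at a time, where a lone library is assumed to vary like the others, the ranges of higher and lower calls were 1335 to 1483 and 1342 to 1438 (naive response), 1274 to 1607 and 1235 to 1716 (HD response), 1100 to 1717 and 1317 to 1836 (HD against naive unstimulated), 1947 to 2164 and 2184 to 2349 (stimulated), 313 to 623 and 347 to 651 (LD against naive), 135 to 230 and 309 to 446 (HD against LD), and 563 to 768 and 621 to 857 (difference). Of 303 called folds of named genes 26 moved by over 1.5 times, by up to 1.81 on the log2 scale (*Gzmd* in HD against LD), and 2 of these, *Egr2* in LD against naive and in HD against LD, lost their call. Only uncalled genes reversed, with ranges of -0.386 to 0.088 for *Tnf* and -0.317 to 0.016 for *Gzmb* in the naive response and -0.334 to 0.102 for *Prf1* in the HD response. The range of *Tbx21* was -0.107 to 0.127 in HD against naive stimulated, -0.546 to 0.092 in LD against naive and -0.088 to 0.55 in HD against LD. It was -0.005 to 0.894 for *Ccl3* in LD against naive, and -0.381 to 0.128 for *Bcl2* and -0.080 to 0.507 for *Mki67* in HD against LD.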

Other observations

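Tests of hypoxia-inducible genes were chosen only after the leading genes had been seen.

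Of 24 hypoxia-inducible genes, a list without the 7 that had prompted it (*Bnip3*, *Ankrd37*, *Narf*, *Mxi1*, *Aldoc*, *Slc16a3* and *Pygl*), 23 were tested: from naive to HD unstimulated 14 were higher and 2 lower, with a median of 1.82 (camera with an estimated correlation, p = 4.47e-04), and after anti-NK1.1 in HD cells 11 were lower and 2 higher, with a median of -1.01 (p = 0.00361). *Ak4* stood at 6.08 ± 0.55 and *Egln3* at 4.42 ± 0.36 in the first comparison, and at -4.37 ± 0.55 and -3.64 ± 0.36 in the second. Without *Rora*, also on the transcription factor list, the medians were 1.845 and -1.054. That 1 deviating HD unstimulated library made the second change is argued against by a median of -0.88, the weaker value with either left out. The list may reflect low oxygen in HD cultures before stimulation, but oxygen was not measured, the first comparison spans both pools, and growth signals that raise glycolytic genes stay open.

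Markers of basophils and mast cells, 11 genes of which *Cma1*, *Prss34*, *Tpsb2*, *Tpsab1* and *Mcpt4* had been seen before, summed to 314 to 410 CPM in naive unstimulated, 112 to 150 in naive anti-NK1.1, 70.9 and 71.8 in LD and 12.7 to 25.7 in HD libraries. No list test is given, since the list holds genes seen first. In the naive response 7 were lower and *Tpsab1* higher (limma, adjusted p = 0.00344), and in LD against naive 5 were lower and *Cpa3* (0.0115) and *Ms4a2* (0.0320) higher. In HD against naive 9 were lower without and 10 with stimulation, and 0 higher, in HD against LD 6 lower and 1 higher, and in the HD response 1 lower. Plasma cell markers, too few for a list test, summed to 78.4 ± 15.2 CPM in naive unstimulated, 88.6 ± 13.1 in naive anti-NK1.1, 172 ± 11.7 in LD anti-NK1.1, 106 ± 1.24 in HD unstimulated and 195 ± 58.5 in HD anti-NK1.1 libraries.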
